A study of Mus musculus with 8 samples.

How the data were processed

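RNA was measured in podocytes isolated from mouse kidney by fluorescence-activated sorting 72 hours after tamoxifen-induced recombination, in 4 control and 4 Mafb knockout samples. Per the labels' protocols, RNA was purified with a Qiagen kit and libraries were made with the NEBNext Ultra RNA kit for Illumina sequencing. The kit as named does not say that strand was kept, and whether the counting used strand is not given in the sources used here. Per the submitters' processing notes, the tools were HISAT2, a splice-aware aligner, and DESeq2, a negative binomial test for counts, with no versions, and the build was GRCm38 (mm10). The program that counted reads per gene is not given in the sources used here.

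The authors deposited a single table of 2287 genes in which every adjusted p-value was below 0.05, the highest being 0.0499. Adjusted p-values were multiplied by their rank and divided by the p-value. The highest result, 14880, was reached within 0.01 in 1951 of the 2286 rows with a p-value above 0. It was taken as the number of genes tested by the authors, so the table holds 15.4% of them. A gene missing from the table was therefore either not tested or not past the authors' threshold, and the table does not say which. The deposited read counts are whole numbers per gene and sample. The deposited normalized signal is the read count divided by a single size factor per sample, between 0.924 and 1.08. The deposited FPKM values are counts per kilobase of the table's gene length and scaled by a sample total, and those totals are proportional to the size factors. The deposited log2 fold changes compare knockout with control and were made by the authors. The deposited gene lengths equalled the merged exons of GENCODE M21 for 2122 of the 2284 genes found there by identifier.

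The sum of counts over the listed genes was 11825145 to 14409046 reads per sample. The totals implied by the FPKM values, 31350875 to 36675012, are the size factors times a constant and so do not give the reads of each library. With sums of this size, counting error is small for abundant genes, and the spread between animals sets the precision. All pairs of replicates differed by more than sampling noise, with a chi-square per gene of 17.96 to 117, so no pair looked like repeat deposits of a single library. The lowest value was that of control replicates 2 and 3, and the next lowest was 51.1, for knockout replicates 1 and 4. Each sample was counted as 1 replicate, as labelled. Samples were grouped by the labels, and the series text describes 4 control and 4 knockout animals.

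Knockout and control were compared with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3 on the deposited counts, with no covariate. The library scale was the authors' size factor times a common total of 33943168 reads. The design fixed before the data were examined named TMM factors; it was changed when the table was seen to hold selected genes only, because TMM factors over genes chosen for a change would assume that most of them did not change. TMM factors are given as an alternative. filterByExpr kept 2284 genes and removed 3. Benjamini-Hochberg adjustment was made over 14880 genes, with every unlisted gene counted as not significant, which was also chosen after the table was seen. This adjustment step is conservative, but dispersions were estimated from the kept listed genes alone. Those genes were selected on these same samples, so the p-values before adjustment may be too small. Log2 fold changes are from edgeR with a standard error (SE) equal to the fold change divided by the square root of F, and levels are normalized counts as mean ± SD.

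The gene lists, 26 in all, were written before the data were examined. For each list, members past the threshold were counted, and again with the p-values adjusted over the list alone, with unlisted members counted as not significant. A list's direction was tested with fry (limma 3.58.1), which asks whether its genes move on balance one way and does not compare them with other genes, for the 18 lists with at least 3 tested members. The planned competitive set test of the edgeR results was not run, because the other listed genes were also chosen for a change. The table was selected on these same samples, so list counts, directions and set tests are not independent evidence. Whether a list held more listed genes than 14880 tested genes would give was computed with the hypergeometric distribution, treating every member as tested, and whether its listed members leaned one way was computed with Fisher's exact test (two-sided) against all listed genes, both with Benjamini-Hochberg adjustment over the lists. Abundant genes reach the table more readily, which limits the first of these tests. The second compares each list with genes that were also chosen for a change, and both treat the genes of a list as independent.

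Named genes follow a rule set before the data were examined. It takes Mafb, Wt1, Nphs1, Nphs2, Podxl, Synpo, Magi2, Tcf21 and Lmx1b where measured, then the 6 highest and 6 lowest log2 fold changes among genes with a gene name other than a provisional symbol, past the threshold with at least 100 normalized counts in the higher group and no overlap between the groups. It then takes up to 4 members of each podocyte list and 2 of each other list, by size of change among members past the threshold with at least 50 normalized counts, filled up to 2 with the most abundant members where fewer passed. Other genes are said to have been chosen after their values were seen, and further members of a fixed list are named as examples of it.

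The method was tested on simulated counts for 2250 genes of the knockout and control comparison, of which 200 were changed. It recovered 83% of the 1.5-fold and 99.0% of the 2-fold changes, with 6 false calls. Most of the 2250 simulated genes were unchanged, whereas the deposited genes were all selected for a change and were adjusted over 14880 genes. These simulated rates therefore do not give the recovery or the false calls of the comparison reported here. Alternatives were median-of-ratios factors over the listed genes, DESeq2 1.42.0, no low-count filter, a mean of at least 100 normalized counts, a replicate block, an adjusted p below 0.01, an absolute log2 fold change above 1, the authors' deposited values, and leaving out each sample in turn. TMM factors, adjustment over the listed genes alone and lists without Mafb were added after the data were seen. Exon overlaps were computed from GENCODE M21 with Python 3.11.15.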

Results

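Podocytes are the epithelial cells whose foot processes and slit diaphragms form the outer layer of the kidney's filter. Podocytes were sorted from mice carrying a tamoxifen-dependent Cre recombinase under Wt1 control and the mTmG reporter, which changes its fluorescent protein after recombination. All samples were taken 72 hours after induction. The 4 knockout samples came from animals with both Mafb alleles floxed. The 4 control samples are titled WT, but their genotype label gives a floxed and an intact Mafb allele, so they are read here as heterozygous after recombination. Which of the 2 holds could not be checked from the table, and every fold change is measured against these samples. The counts summed over the 2287 listed genes were 14409046, 13127773, 13366631 and 13798259 reads in control replicates 1 to 4, and 12542262, 11825145, 13409102 and 12791209 in knockout replicates 1 to 4.

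The comparison asks which podocyte transcripts depend on MAFB, a basic leucine zipper transcription factor of the large Maf family, which the series places beside WT1 at podocyte promoters. Mafb itself (ENSMUSG00000074622, GRCm38 chromosome 2, 160363703 to 160367065, a gene with a single exon) fell from 34056 ± 3342 normalized counts in controls to 1122 ± 238 in knockouts (mean ± SD, n = 4 each), 30.4-fold lower. The control samples held 33691, 34880, 37863 and 29790 normalized counts and the knockout samples 1289, 877, 962 and 1360, so the labels and the targeted gene went together in every sample. Its log2 fold change was -4.92 ± 0.17 (SE; edgeR adjusted p = 2.13e-06). Which part of the exon is floxed is not given in the sources used here. Wt1 was not among the listed genes.

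Nphs1, Nphs2, Magi2 and Ddn fell in the knockout, to 30.3%, 33.7%, 32.5% and 31.0% of the control level, while other genes of their list, such as Kirrel2 and Tjp1, rose. Nphs1, which encodes nephrin, the main adhesion protein of the slit diaphragm, went from 208076 ± 10782 to 63136 ± 7225 normalized counts (log2 fold change -1.72 ± 0.10). Nphs2, which encodes podocin, its membrane scaffold, went from 503490 ± 84116 to 169636 ± 23270 (-1.57 ± 0.15). The scaffold gene Magi2 fell by 1.62 on the log2 scale and Ddn, which encodes the podocyte and neuronal protein dendrin, fell by 1.69. The edgeR adjusted p-values of these 4 genes were 2.82e-05, 0.000488, 2.82e-05 and 2.54e-05. Nphs1 overlaps the antisense gene Nphs1os and the pseudogene Rps12-ps4, both listed as lower, and Ddn overlaps a listed antisense gene, so the values of these minor partners are uncertain without strand.

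Of the 31 slit diaphragm and foot process genes, 16 were listed, of which 9 fell, 5 rose and 2 did not pass the test (9 lower and 5 higher; 11 lower and 5 higher when adjusted over the list alone). Beyond the genes above, Synpo, which encodes the actin-binding protein synaptopodin, fell (-0.70 ± 0.08, adjusted p = 0.00181), and so did Arhgap24, a Rac-directed GTPase-activating protein (-0.97 ± 0.06, adjusted p = 5.89e-05). The genes that rose were Kirrel2, a nephrin-like adhesion protein (1.30), Inf2, a formin (0.79), Dag1, dystroglycan (0.54), Tjp1, the junction protein ZO-1 (0.50), and Actn4, alpha-actinin-4 (0.38), all as edgeR log2 fold changes. Podxl, which encodes podocalyxin, the main sialomucin of the podocyte surface, stood at 962988 ± 25021 and 819174 ± 28427 normalized counts (-0.23 ± 0.07) and did not pass (adjusted p = 0.0874). Without control replicate 2 or without control replicate 3, 3 of the list's genes passed as higher and 8 as lower. Over the 8 fits without 1 sample, Kirrel2, Dag1 and Tjp1 passed as higher in all, Inf2 in 6 and Actn4 in 2.

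**Figure D1:**
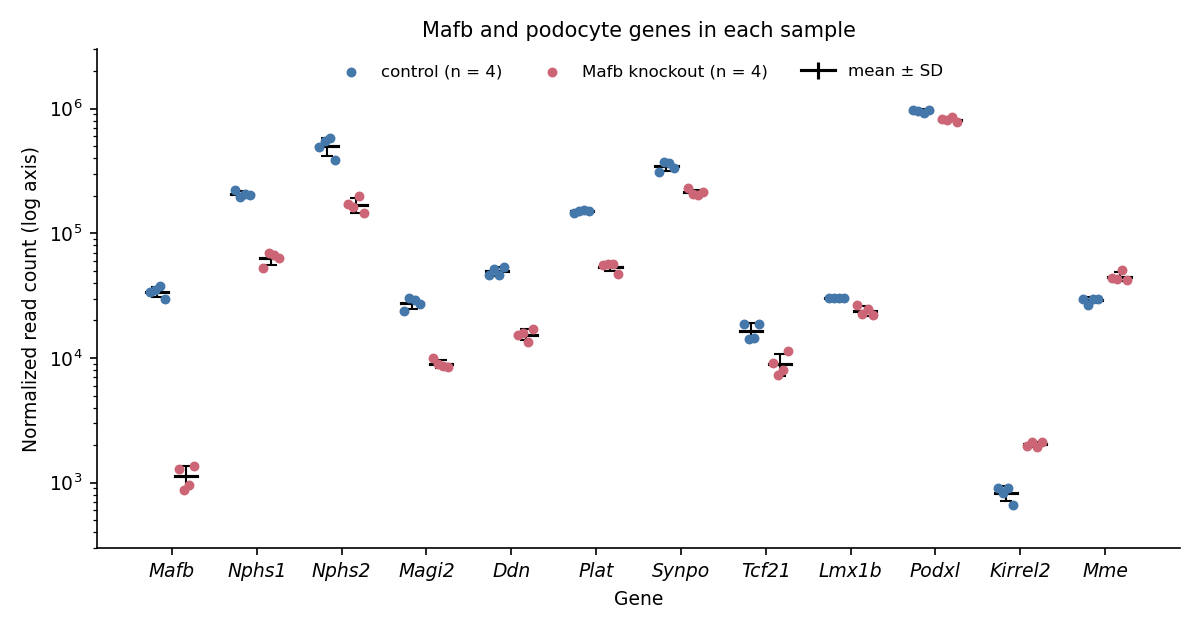
Normalized read count (vertical log axis) of 12 genes (horizontal axis) in each of 4 control (blue) and 4 Mafb knockout (red) samples; points are samples, thick lines are means and error bars are the SD. The knockout samples lie below every control sample for Mafb and for Nphs1, Nphs2, Magi2, Ddn and Plat, and above them for Kirrel2 and Mme.

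Other podocyte markers also changed in both directions. Of 29, 17 were listed, of which 11 fell, 2 rose and 4 did not pass (13 lower and 4 higher when adjusted over the list alone; past as higher were 1 without control replicate 2 or 3 and 3 without knockout replicate 1 or 3). Plat, tissue plasminogen activator, fell from 150853 ± 3139 to 54091 ± 4602 normalized counts (-1.48 ± 0.08, edgeR adjusted p = 2.14e-05). Tdrd5 fell by 1.42, Sema3g, a secreted semaphorin, by 0.92 and Rhpn1, a Rho-binding protein, by 0.75 on the log2 scale. Vegfa, the growth factor on which the neighbouring endothelium depends, fell by 0.47. The genes that rose were Mme, the membrane peptidase neprilysin (0.63), and Ildr2 (0.47). The adjusted p of Rhpn1 was 0.0233 and reached up to 0.0728 when single samples were left out; it was not past the threshold without control replicate 2 or 3 or without knockout replicate 1, 2 or 4.

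Among 22 podocyte transcription factors, 8 were listed, of which 4 fell, 2 rose and 2 did not pass (5 lower and 3 higher when adjusted over the list alone). Their median log2 fold change was -0.27 and fry placed the list lower, while the mean was 0.04. The list holds Mafb, the gene deleted by design; without it the median was -0.19 and fry still placed the list lower (adjusted p = 0.00585). Besides Mafb, Zfp423 fell by 1.48, Tcf21, a basic helix-loop-helix factor of podocyte development, by 0.88, and Lmx1b, the nail-patella syndrome factor, by 0.35 on the log2 scale. Zbtb16 rose from 22.4 ± 10.9 to 989 ± 1567 normalized counts (5.45 ± 1.35, edgeR adjusted p = 0.0419) and Klf15 from 395 ± 103 to 1229 ± 889 (1.64 ± 0.42, adjusted p = 0.0487), both with a knockout spread set by replicate 2. Without knockout replicate 2 the log2 fold changes were 3.23 for Zbtb16 and 0.99 for Klf15. Over the 8 fits without 1 sample, the highest adjusted p was 0.124 for Zbtb16 and 0.138 for Klf15, and Lmx1b reached 0.0549 (past the threshold except without control replicate 2 or 3). Zbtb16 was not past it without any single control sample or without knockout replicate 1, and Klf15 was past it only without knockout replicate 2.

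Among 63 genes of inherited nephrotic syndrome and proteinuria, 17 were listed, of which 9 fell and 5 rose (11 and 5 when adjusted over the list alone); most are named above, and Cubn, the endocytic receptor cubilin, rose from 24.5 ± 10.4 to 95.01 ± 47.1 normalized counts. Of the 8 Maf family genes, 3 were listed, and Mafb and Mafa fell (Mafa -0.69 ± 0.15, edgeR adjusted p = 0.0290), with 3 lower when adjusted over the list alone. Without control replicate 2 or 3, 0 nephrotic syndrome genes passed as higher, without control replicate 1 there were 3, and without control replicate 4 or knockout replicate 2, 3 or 4 there were 2. The adjusted p of Mafa reached up to 0.0880 and it was past the threshold only when control replicate 1 or knockout replicate 3 was the sample left out. The adjusted p of Cubn reached up to 0.0703, and it was not past the threshold without control replicate 2, 3 or 4.

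Secreted and guidance factors changed in both directions. Of 35 such genes, 10 were listed, of which 5 fell and 2 rose (6 and 4 when adjusted over the list alone). Angptl2, an angiopoietin-like secreted protein, fell from 73071 ± 6648 to 23579 ± 3061 normalized counts (-1.63 ± 0.11, edgeR adjusted p = 8.53e-05), while Sema3f (0.57) and Igfbp7 (0.29) rose. As higher, 0 of this list passed without any single control sample or without knockout replicate 1, and 1 without knockout replicate 2 or 3.

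Adhesion and cytoskeletal genes moved in both directions. Of 31 integrin and focal adhesion genes, 11 were listed, of which 4 fell and 1 rose (4 and 6 when adjusted over the list alone). Itgb5, integrin beta-5, fell by 0.68 on the log2 scale (edgeR adjusted p = 0.00125), and Itga3, the podocyte laminin receptor, by 0.64. Flna, the actin cross-linker filamin A, rose from 8090 ± 1132 to 20410 ± 7292 normalized counts (1.34 ± 0.26, adjusted p = 0.0166, and 0.0592 without control replicate 3). The median and mean of this list were 0.28 and 0.12 although fry (limma) placed it lower, without passing (adjusted p = 0.561); 2 genes passed as higher without knockout replicate 1 or 2. Of 42 Rho and actin regulators, 12 were listed, of which 7 rose and only Arhgap24 fell (10 and 1 when adjusted over the list alone). Tpm1, tropomyosin 1, rose by 0.81 ± 0.18 and Actn1 and Myh9, the non-muscle myosin heavy chain, by 0.63 and 0.43. As higher, 2 of these regulators passed without control replicate 2 or 3 or knockout replicate 2, 3 without control replicate 1 or knockout replicate 3, and 4 without knockout replicate 4; Tpm1 (adjusted p = 0.0268) was not past the threshold without control replicate 1, 2 or 3 or knockout replicate 2 or 3. Of 29 basement membrane and matrix genes, 8 were listed; Fras1 (0.71) and the proteoglycan gene Agrn (0.27) rose and Col18a1 (-0.66) fell, and 2 higher and 1 lower passed when adjusted over the list alone. Agrn lost its call in all 8 fits without 1 sample, Fras1 and Col18a1 in none of them, and 3 genes passed as lower without knockout replicate 3.

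Endoplasmic reticulum chaperone and unfolded protein response genes were all lower where listed. Of 26, 13 were listed, all 13 lower by the authors' deposited fold changes (Fisher's exact test against all listed genes, adjusted p = 0.0019), and 4 fell in the edgeR test (13 when adjusted over the list alone). These were the disulphide isomerases Pdia6 (-0.65 ± 0.14) and Pdia4 (-0.64 ± 0.15), Dnajc3 (-0.45) and Atf6 (-0.28). Hspa5, which encodes the chaperone BiP, stood at 47089 and 23429 normalized counts (-1.01) with an edgeR adjusted p of 0.0640. The number that passed was 0 without control replicate 2 or 3 or knockout replicate 1, 1 without knockout replicate 2, 2 without control replicate 1 or knockout replicate 4, and 7 without knockout replicate 3. Pdia4 was not past the threshold without control replicate 2, 3 or 4 or knockout replicate 1, 2 or 4, nor Pdia6 without control replicate 2 or 3 or knockout replicate 1. Of 13 mitochondrially encoded genes, 8 were listed, all higher, and 4 rose, including mt-Nd6 (0.42 ± 0.09) and mt-Co1 (0.40 ± 0.08), with 8 when adjusted over the list alone. For these genes it was 0 without control replicate 2 or 3 or knockout replicate 1 or 4, 1 without control replicate 4, 2 without knockout replicate 3, and 7 without knockout replicate 2. Neither mt-Nd6 nor mt-Co1 was past it without control replicate 2, 3 or 4 or knockout replicate 1 or 4.

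**Figure D2:**
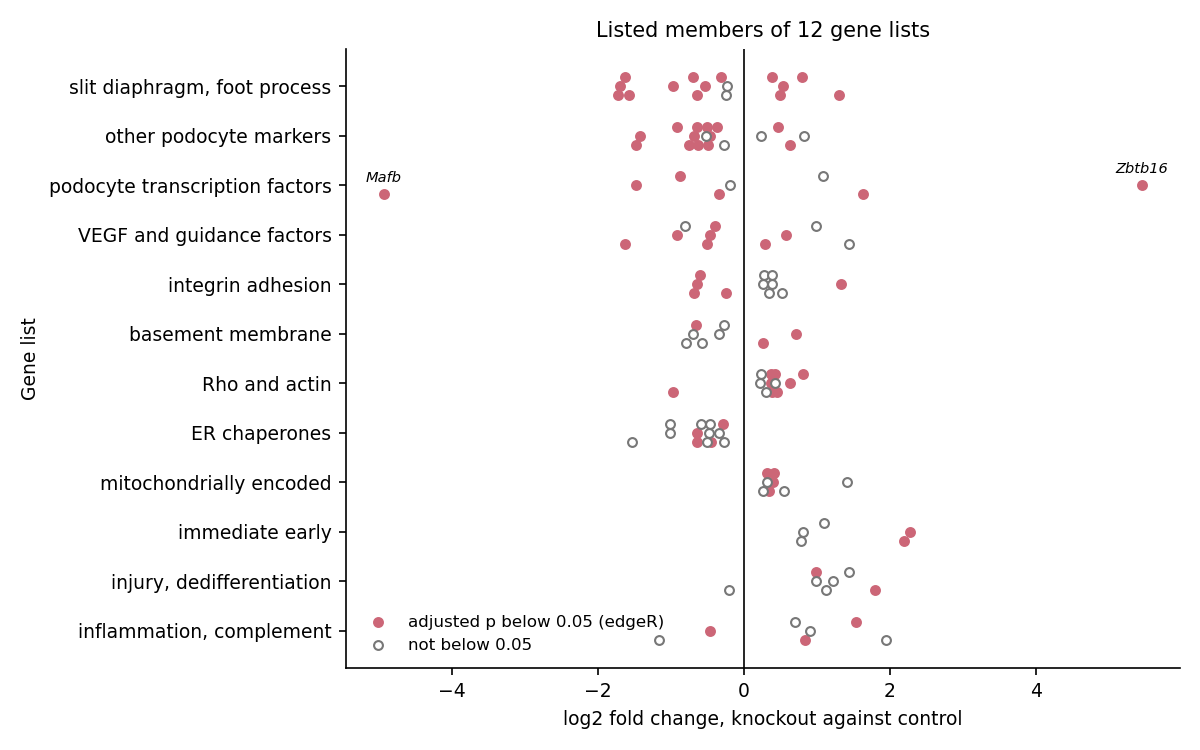
Log2 fold change of knockout against control (horizontal axis) for the listed members of 12 gene lists (vertical axis); filled points had an edgeR adjusted p below 0.05 and open points did not. Podocyte genes lie on both sides of 0, ER chaperones only below it and mitochondrially encoded genes only above it.

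Immediate early, injury, inflammation and signalling genes each had members past the threshold. Of 25 immediate early genes, which respond within minutes to hours of cell handling, 5 were listed, all higher, of which Gadd45b (2.28 ± 0.42) and Junb (2.19 ± 0.49) rose; both were past the threshold when adjusted over the list alone. Both were highest in knockout replicate 2, and without it the log2 fold changes were 1.83 and 1.39. Of 32 injury and dedifferentiation genes, 7 were listed, and Cyr61, a YAP target, rose by 1.79 ± 0.39 and S100a6 by 0.99 ± 0.24. Of 37 inflammatory and complement genes, 8 were listed, of which the complement component C3 (1.53 ± 0.33) and Irf1 (0.83 ± 0.20) rose and Cd55, a complement regulator, fell (-0.46). Of 28 Notch and Wnt genes, 7 were listed, of which Nkd1 (1.69 ± 0.39) and Hey2 (0.80) rose and Wnt4 (-1.25 ± 0.25) and Ctnnb1 (-0.21) fell. Adjusted over the list alone, the counts were 2 higher for injury, 4 higher and 1 lower for inflammation, and 2 higher and 2 lower for Notch and Wnt genes. Without control replicate 2 or 3, none of these 4 groups had a member past the threshold as higher. Immediate early genes had 1 without control replicate 1 or 4, where Junb was not past it (adjusted p up to 0.0936 over the fits without 1 sample). Injury genes had 0 without control replicate 4 or knockout replicate 2, 1 without control replicate 1 or knockout replicate 1 or 3, and 3 without knockout replicate 4. Cyr61 lost its call in 5 of the 8 fits (without control replicate 2, 3 or 4 or knockout replicate 2 or 3) and S100a6 in all but the fit without knockout replicate 4, with adjusted p up to 0.0803 and 0.0903. Inflammation genes had 0 as higher without control replicate 4 or knockout replicate 2, 1 without knockout replicate 1 or 4, and 2 as lower without knockout replicate 3. C3 and Irf1 lost their calls without control replicate 2, 3 or 4 or knockout replicate 2 or 4, C3 also without knockout replicate 3 and Irf1 without knockout replicate 1. Notch and Wnt genes had 0 as higher without knockout replicate 1, 2 or 4 and 1 without control replicate 1 or 4, and Nkd1 was not past the threshold without control replicate 2, 3 or 4 or knockout replicate 1, 2 or 4. As lower, 0 Notch and Wnt genes passed without knockout replicate 4, where the adjusted p of Wnt4 was 0.0592, and 1 without control replicate 2, 3 or 4 or knockout replicate 1, 2 or 3.

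In the smaller lists, Ccnd3 (0.48 ± 0.10) and Ccne1 (1.75 ± 0.37) were the only 2 of 33 cell cycle genes listed and both rose. Of 20 antioxidant genes, 4 were listed, of which Nqo1 rose (1.22 ± 0.22) and Hmox1, heme oxygenase 1, fell (-0.82 ± 0.13). Of 24 sterol and fatty acid synthesis genes, 3 were listed and Scd1, a fatty acid desaturase, rose (1.18 ± 0.22), while Srebf1 stood at 0.18 ± 0.05 and did not pass. Adjusted over the list alone, the counts were 2 higher for the cell cycle, 2 higher and 1 lower for antioxidant genes and 1 higher for lipid synthesis. Neither cyclin gene passed without control replicate 2 or 3 or knockout replicate 4, nor did Ccne1 without control replicate 1.

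Markers of other kidney and blood cells were mostly absent from the listed genes. Of 142 markers of 8 other cell types, 13 were listed. In the edgeR test Cubn of the proximal tubule, Tagln of mesangium and smooth muscle (48.8 ± 16.7 to 125 ± 35.0 normalized counts) and Gsn of fibroblasts rose. Krt7 of parietal epithelium (5385 ± 586 to 2394 ± 290), Rgs5 of pericytes (436 ± 92.3 to 204 ± 26.1) and Cd74 of immune cells (109 ± 27.8 to 46.3 ± 17.96) fell. Gpx3 (1.31, adjusted p = 0.0504), Akap12 (0.43), Kitl (-1.27), H2-Ab1 (-1.08), Fbln5 (0.74), and Ptn (-0.78) and Art3 (-1.41) of the mesangium list did not pass. Of these lists fry could test only mesangium and smooth muscle, with 4 tested genes, and placed it lower (adjusted p = 0.0333), although Tagln rose. Adjusted over each list alone, Akap12, Krt7, Tagln, Rgs5, Cubn, Gsn and Fbln5 passed. No marker of the distal nephron or of erythrocytes was listed. Only Krt7 and Rgs5 were past the threshold in each of the 8 fits without 1 sample; the highest adjusted p was 0.0703 for Cubn, 0.0956 for Tagln, 0.0804 for Gsn and 0.129 for Cd74. All 4 lost the call without control replicate 2 or 3, Cubn also without control replicate 4, Tagln and Cd74 without control replicate 1 or knockout replicate 1, 2 or 4, and Gsn without knockout replicate 2, 3 or 4.

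Most of the largest changes lay outside these lists. They are ranked here among genes past the edgeR threshold with a gene name other than a provisional symbol, at least 100 normalized counts in the higher group and no overlap between the groups, so larger values such as that of Cebpd (4.16, adjusted p = 0.0562) are left out. After Mgat5b, a glycosyltransferase that fell from 3832 ± 1103 to 40.7 ± 24.7 normalized counts (-6.55 ± 0.44, edgeR adjusted p = 9.85e-05), and Mafb, the lowest log2 fold changes were those of Clic3, an intracellular chloride channel protein (19416 ± 1850 to 802 ± 126, -4.60 ± 0.14), Cd5 (-4.27), Calca, the calcitonin gene (-3.85), and Lctl (-3.17). After Zbtb16, the highest were those of Mfsd2a, a lysophospholipid transporter (5.45 ± 2.55 to 155 ± 178 normalized counts, 4.80 ± 0.95), Nptx1, neuronal pentraxin 1 (79.4 ± 36.5 to 864 ± 228, 3.44 ± 0.32), Ckb, creatine kinase B (2.78), the clock gene Per2 (2.69), and Selenbp1 (2.67). Knockout replicate 2 was far above the other knockout samples for Mfsd2a and Selenbp1, and without it their log2 fold changes were 3.59 and 1.88. The log2 fold change of Cd5 ranged from -5.56 to -3.92 over the 8 fits without 1 sample. Calls were lost without control replicate 2 or 3 for Mfsd2a, Selenbp1 and Per2, without control replicate 1 for Mfsd2a and Per2, without control replicate 4 for Selenbp1, and without knockout replicate 2 or 4 for Per2, with adjusted p up to 0.0655 for Mfsd2a, 0.0674 for Selenbp1 and 0.0831 for Per2. Mgat5b, Clic3, Cd5, Calca, Lctl, Nptx1 and Ckb kept their calls in each of the 8 fits. With the replicate block, Ckb was not past the threshold (edgeR adjusted p = 0.0655).

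**Figure D3:**
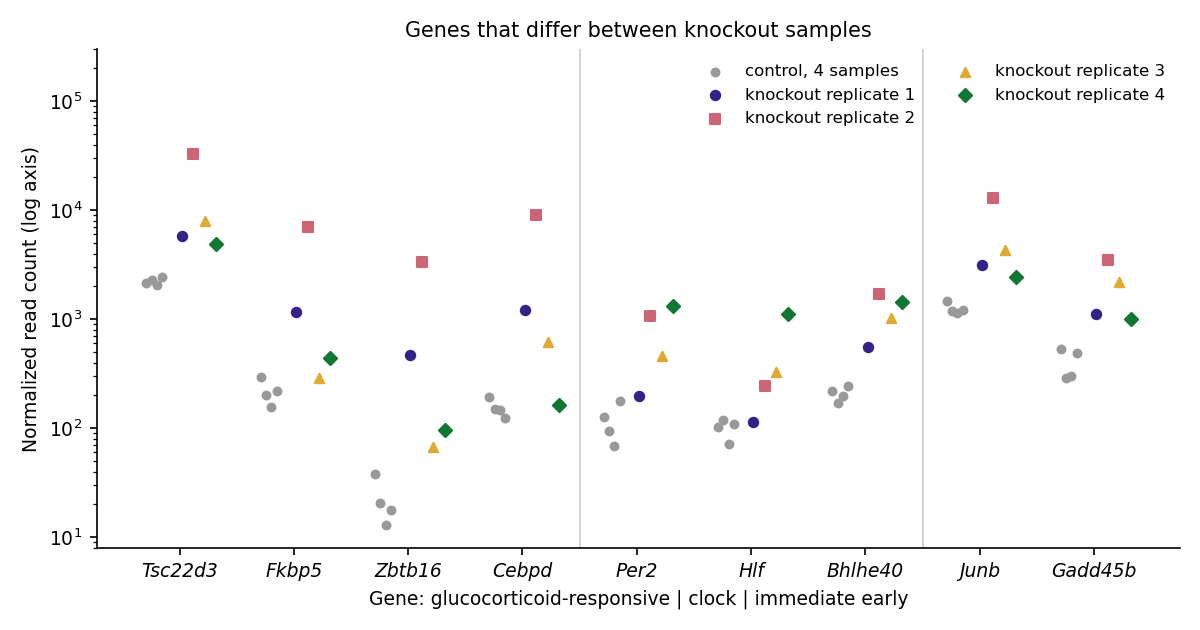
Normalized read count (vertical log axis) of 9 genes (horizontal axis), chosen after their values were seen, in 4 control samples (grey) and knockout replicates 1 to 4 (coloured symbols). Knockout replicate 2 is the highest knockout sample for Tsc22d3 (32526), Fkbp5, Zbtb16, Cebpd, Junb and Gadd45b, and knockout replicate 4 for Per2 and Hlf.

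**Figure D4:**
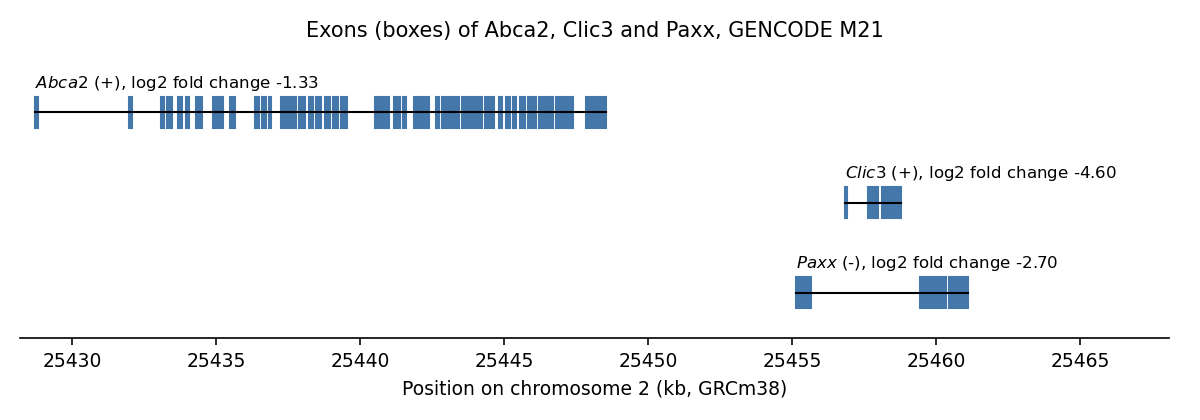
Exons (boxes) of Abca2, Clic3 and Paxx, the last being a gene on the opposite strand, along GRCm38 chromosome 2 (horizontal axis, kb), with the edgeR log2 fold change of each. Clic3 lies in an intron of Paxx, no exons of the 3 genes overlap, and all 3 fell (-4.60, -2.70 for Paxx and -1.33 for Abca2); Paxx and Abca2 were chosen after their values were seen.

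Over the whole table, 1232 of the 2284 tested genes changed in the edgeR test at an adjusted p below 0.05, 577 higher and 655 lower. The authors' deposited table calls all 2287, with 1178 higher and 1109 lower. Of the 18 lists with at least 3 tested genes, fry found 13 that moved on balance one way, which is not independent evidence because the table was selected on these samples. Of the 13, 3 hold Mafb, whose fall the design sets. With Mafb left out of the lists, a setting added after seeing the data, 11 of 17 moved one way. Podocyte transcription factors and nephrotic syndrome genes still passed fry without it (adjusted p = 0.00585 and 9.89e-05), and the Maf family had too few genes left to test. Lipid synthesis genes, a list that never held Mafb, went from a fry adjusted p of 0.0493 over 18 lists to 0.0504 over 17. By the hypergeometric test, 7 lists reached the table more often than tested genes at large. These were slit diaphragm genes (16 of 31 listed, adjusted exact p = 3.57e-05), other podocyte markers (17 of 29, 2.97e-06), ER chaperones (13 of 26, 0.000323), mitochondrially encoded genes (8 of 13, 0.00124), integrin genes (11 of 31, 0.0246), podocyte transcription factors (8 of 22, 0.0486) and nephrotic syndrome genes (17 of 63, 0.0486). The last 2 hold Mafb and did not pass without it (adjusted p = 0.0973 and 0.0840). The number of changed genes fell to 514 without control replicate 2, 535 without control replicate 3, 728 without knockout replicate 4 and 802 without knockout replicate 1; the number higher was then 182, 196, 325 and 364, and 350 without control replicate 4, and the number lower was 332, 339 and 403 in the first 3 of these.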

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

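The tests of knockout replicate 2 alone and of collection time, the gap of the immediate early genes, and the lists of glucocorticoid-responsive and clock genes, were chosen after the result was seen; the comparison of immediate early genes by mean difference was not. Of 176 groups of 4 values examined, 17 had a sample whose gap to its nearest neighbour exceeded Dixon's 95% critical value as a share of the group's range. Gaps were taken on untransformed normalized counts. Chance gives about 5% of groups only if such values are normally distributed, which was not tested. On a log2 scale, on which these gaps were not computed, a high sample stands apart less. Of the 17, 10 were knockout replicate 2. That sample was the highest knockout sample for Klf15 (gap 0.972 of the range), Gadd45g (0.929), Selenbp1 (0.913), Nfkbia (0.903), Tsc22d3 (0.891), Cebpd (0.883), Zbtb16 (0.876), Ddit4 (0.874), Fkbp5 (0.869) and Mfsd2a (0.831). For Tsc22d3 it held 32526 normalized counts against 7947 in the next knockout sample, and for Cebpd 9097 against 1205. Of the 10 genes, all but Selenbp1 belong to the glucocorticoid-responsive list, which was chosen after the result was seen. The 5% therefore gives no fair expectation for this sample.

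The other samples that stood apart were control replicate 4, highest for Cry2 (0.926), and knockout replicate 1, lowest for Cry2 (0.836). Knockout replicate 4 was lowest for Plat (0.928, 47202 against 56089 normalized counts). Krt7 was lowest in control replicate 1 (0.856) and, among knockouts, in knockout replicate 3 (0.913). Irf1 was highest in control replicate 1 (0.832), and Tagln was lowest in knockout replicate 3 (0.841).

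Of 40 glucocorticoid-responsive genes 11 were listed, all higher in the knockout with 5 past the edgeR threshold, and of 13 clock output and period genes 7 were listed, all higher with 4 past it (2 without knockout replicate 2 and 3 without knockout replicate 4), while Rora (-0.33) and Csnk1d (-0.19) were lower and did not pass; the first group stood 3.99 log2 units above the control mean in knockout replicate 2 and 1.87, 1.57 and 0.90 in replicates 1, 3 and 4, and the second was highest in replicate 4 (2.51). Knockout replicate 2 alone is argued against as the whole source for glucocorticoid-responsive genes, since without it 6 of the 11 genes passed as higher. Adjustment was over the 14880 genes, with unlisted genes counted as not significant. For the other 5, which did not pass, it stays open. Their log2 fold changes without that sample ran from 0.35 (Klf9) to 2.09 (Cebpd), and Irs2 was highest in knockout replicate 3 (4360 normalized counts, 4177 in replicate 2). A response to tissue dissociation cannot be told apart from a knockout effect. The 5 listed immediate early genes were on average 1.34 ± 0.18 log2 units (SE over genes) higher in knockout replicate 2 than in the other knockout samples. This met the rule set in advance for such a response, a difference above 2 SE. The rule sets a single sample against the rest, with an error over genes and not over samples, so it was read as undecided after the value was seen. On the log2 scale, the gap to the next sample was 0.803 of the range over the 4 knockout samples, below Dixon's 95% critical value. The gaps of single genes above were taken on untransformed normalized counts and cannot be compared with it. The gap of the immediate early genes was not computed on that untransformed scale. Collection at another time of day cannot be told apart from a knockout effect, because 0 of 5 clock genes of the opposite phase were listed and sampling times were not used here. The Mafb genotype, the difference the design names, stays open as well and was not tested separately.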

How the results depend on the processing

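No gene past the threshold changed sign under any alternative. DESeq2 called 2109 genes (1058 higher, 1051 lower) and the authors' deposited values 2287 (1178 and 1109). Adjusted over the listed genes alone, a setting added after seeing the data, 2284 passed (1175 and 1109). An adjusted p below 0.01 left 380 (114 and 266), and an absolute log2 fold change above 1 left 303 (168 and 135), by construction. TMM factors on the listed genes, also added later, gave 1257 (683 and 574), and median-of-ratios factors 1297 (549 and 748), so which direction held more genes depended on the scaling. The median over genes of the shift in log2 fold change from the main fit was 0.0194 with TMM factors and -0.0236 with median-of-ratios factors. These were the largest such shifts upward and downward over the alternatives. The replicate numbers did not pair the samples, since same-numbered samples had correlations of -0.22, -0.08, -0.04 and 0.09 and only number 4 matched its own best; the replicate block left 480 genes (171 and 309) and 8 lists, with Mafb at -4.94, and 468 of the 480 were shared with the unblocked fit.

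Leaving out single samples gave 514 to 1019 changed genes, 182 to 482 higher and 332 to 575 lower; 9 to 12 lists moved one way (11 with all samples and Mafb left out of the lists), and Mafb ranged from -5.03 to -4.82. The cause of the low counts without control replicate 2 or 3 was not tested. Each of these fits leaves out 1 sample, so the number of samples does not explain the difference between them. Control replicates 2 and 3 were the most alike pair of replicates (chi-square per gene 17.96, the next lowest being 51.1), and dropping either of them breaks up that pair. Of the 56 named genes past the threshold, 28 passed in each of these 8 fits and 28 lost the call in 1 or more. With the replicate block, 30 of the 56 were past the threshold and 26 were not. Planned competitive set tests, with preset or estimated correlation, were not run on a table of selected genes, and pseudocounts did not apply to counts. Genes outside the table set no limit on what did not change.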

Other observations

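The tests on Paxx and Abca2, on podocyte share and other cell types and on the surroundings of Mafb, and the comparison with neighbouring genes, were chosen after the results were seen; the tests on all overlapping pairs and on other splits of the samples were not. H2-Q6, H2-Q7, H2-Q5 and H2-Q10, major histocompatibility class I genes on chromosome 17 that were chosen after their values were seen and not tested as a group, each fell in the knockout. H2-Q6 went from 124426 ± 29085 to 25504 ± 12569 normalized counts (mean ± SD, n = 4 each; log2 fold change -2.29 ± 0.33 SE, edgeR adjusted p = 0.00477). The log2 fold changes of the others were -1.78 ± 0.21 (H2-Q7), -1.67 ± 0.19 (H2-Q5, annotated as a polymorphic pseudogene) and -2.39 ± 0.37 (H2-Q10). These genes are near-identical copies, so how reads were divided between them is uncertain. Slc27a3, a fatty acid transport protein, fell from 6855 ± 814 to 1599 ± 110 normalized counts (-2.10 ± 0.09).

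Clic3, Paxx, a DNA end-joining factor, and Abca2, a lipid transporter, lie within GRCm38 chromosome 2, 25428703 to 25461094, and fell together. Paxx went from 13496 ± 1019 to 2084 ± 133 normalized counts (-2.70 ± 0.07, edgeR adjusted p = 8.12e-07) and Abca2 from 31264 ± 500 to 12465 ± 494 (-1.33 ± 0.05, adjusted p = 3.40e-06).

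Clic3 lies within an intron of Paxx on the opposite strand. The annotated exons of Clic3 and Paxx share 0 bases and those of Abca2 share 0 bases with either, which argues against reads shared at annotated exons. Reads that run past the annotated exons were not tested, and whether the counting used strand is not given. Among listed genes whose exons do overlap on opposite strands, 84.2% of 38 pairs changed in the same direction, against 50.05% by chance (exact binomial p = 2.43e-05), so shared reads may shape other pairs. Opposite-strand listed neighbours within 10 kb and without overlap also changed in the same direction in 64 of 83 pairs (77.1%), so the first share is not specific to shared reads. A common effect of the knockout on this region stays open and was not tested separately.

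Of the 33 listed podocyte markers, 20 fell and 7 rose. A smaller podocyte share in the knockout sorts would lower all of them alike if the other cells held none of these transcripts. The 7 markers that rose go against it as the whole source only if other cells lack their transcripts. That condition was not tested, so these markers do not decide it. Without control replicate 2 or 3 the number of markers past as higher was 4. Kirrel2, Mme, Dag1 and Tjp1 passed as higher in each of the 8 fits without 1 sample. RNA from other cell types as the whole source would likewise dilute all markers by a single factor, under the same condition. These 4 markers argue against it only if the other cells did not express them. A part played by such RNA could not be told apart from this pattern: of the 6 listed markers of other cell types past the threshold, 50% were lower (exact binomial 95% interval 11.8% to 88.2%), and 6 are too few to decide. Gsn and Krt7, at 57795 and 2394 normalized counts in the knockout, were the most abundant of the 6. The purity of the reporter-based sort was not tested. The Mafb genotype stays open as the difference the design names.

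Flanking DNA carried along with the floxed allele would raise the share of listed genes near Mafb. Within 20 Mb of Mafb 10.7% of protein-coding genes were listed, and elsewhere 9.57% (odds ratio 1.13, Fisher's exact test, two-sided p = 0.432), which does not decide it. Gm826 (chromosome 2, 160311393 to 160334162), downstream of Mafb on the same strand and chosen after its values were seen, rose (1.01 ± 0.14).

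The 35 splits of the 8 samples into 4 and 4 include 1, the real split, with 1232 changed genes, and the highest of the other splits had 0. The genes were selected on the real split, so this count cannot say whether chance is excluded.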
